A study of Arabidopsis thaliana with 12 samples.

How the data were processed

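Messenger RNA was sequenced from whole Arabidopsis thaliana seedlings of 4 transgenic lines, each in the mute-3 loss-of-function background. Per the labels, a library was made from 50 pooled seedlings at 2 days post-germination, with 3 biological replicates per line and 12 libraries in all. Seedlings grew on medium with 1% sucrose at 21 °C under 16 h of light (70 µmol m-2 s-1) and 8 h of dark, and a TruSeq stranded mRNA kit was used.

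MUTE is the bHLH transcription factor that ends the self-renewing phase of the stomatal lineage and commits its cells to become guard mother cells. The reference line (MUTE, line 1) carries the wild-type protein. MUTEv5#2 (line 2) and MUTEv5#5 (line 5) carry the same R10W protein, and MUTEPPP#3 (line 3) carries H3P, E7P and R11P; residues are numbered as the submitters number them. Each allele is driven by the MUTE promoter.

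The authors deposited counts: 1 whole number per gene and library, in a column that the file headers call a read count. The authors list FastQC, Trimmomatic 0.38, HISAT2 2.1.0, Bowtie2 2.3.4.1, StringTie 2.1.3b and DESeq2, with the TAIR10 build. Which of these made the counts, the strand setting and the treatment of read pairs are not given in the sources used here. The table holds 23098 entries, of which 23071 match a gene of the reference annotation by identifier. The remaining 27 name no gene, held at most 5.96e-04% of any library's counts, and were left out. The lowest value in every library was 1 and no entry was at 0, so genes without reads in some library are absent from the table, or 1 was added to every value. Of the entries, 80 stood at 1 in all 12 libraries. Counts of reads would seldom give this, which argues against absent genes as the only explanation. How the values were made is not given. Of the 261 gene list entries, 239 were present, and 22 lists were tested.

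Library totals ran from 117868477 to 152600239 counts, so that 1 count equals at most 0.00915 CPM, counts scaled by the normalised library size to a total of 1e6. Counting error is small at this depth: replicates differed by 81.9 to 303 times the chi-square per degree of freedom that counting alone gives. Replicates of a group correlated at a Pearson r of 0.973 to 0.992 over genes, which are not independent replicates. Libraries of different lines could be as alike. MUTE replicate 1 correlated at 0.986 with MUTEv5#5 replicate 1, and at 0.978 and 0.973 with MUTE replicates 2 and 3. The common biological coefficient of variation was 0.215.

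Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter (22636 genes tested, 435 left out) and all 12 libraries in a single fit of 4 group means. The 6 pairwise comparisons of the groups were tested, and p-values were adjusted by Benjamini-Hochberg over all genes tested in each comparison, with a threshold of 0.05. Fold changes are on the log2 scale and named for the first group over the second. CPM use the TMM-scaled library totals and are given as mean ± SD over 3 libraries; SE is the standard error of a log2 fold change.

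Gene lists were tested with camera (limma 3.58.1, two-sided) with a preset correlation of 0.01 between genes, adjusted over 132 tests of 22 lists in 6 comparisons. The lists cover the early stomatal lineage, the guard mother cell step, mature guard cells, stomatal signalling, mitosis, DNA replication, epidermis and cuticle, trichome and hair patterning, root cell types, photosynthesis, seed storage and maturation, lipid reserve mobilisation, cold and abscisic acid response, heat shock, salicylic acid defence, jasmonate and wounding, morning and evening clock genes, auxin response, cytokinin response, flavonoid synthesis and iron deficiency. Members were also counted with p-values adjusted over the list alone. Each list was tested again with a correlation estimated from its own genes; only the guard cell lists of MUTEv5#2 and MUTEv5#5 against MUTE kept their calls then, so that the other list results rest on the preset value. In every list called, the median, the mean and the test had the same sign.

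Named genes follow a rule: MUTE; in each comparison with MUTE, the 6 genes that rose and the 6 that fell most with an adjusted p under 0.05, at least 1 CPM on average and no overlap between the groups (3 and 3 between variant lines); up to 4 members of each of the 4 stomatal lists and up to 3 of each other called list with the smallest p; and the 5 shared rises and 5 shared falls with the smallest largest p. The comparisons, tests, lists, this rule and the alternatives, apart from those said to be added, were set before the data were examined. Other members of the lists are named where they passed the test. Genes outside the rule and the lists are said to be chosen after their values were seen.

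The alternatives were DESeq2 1.42.0, limma-voom, RLE scaling, library totals as the only scaling, no filter on low counts, at least 10 counts in at least 6 libraries, only the compared groups in the fit, replicate number as a block, a test against a fold of 1.2, fry in place of camera, and each library left out in turn; a group then has 2 libraries and shares the spread of the others. Added after the data were seen were a clock index of each library as a covariate (mean log2 CPM of the morning list minus that of the evening list), the share of ribosomal and organelle reads as a covariate, the omission of the 2 libraries with the highest clock index, and libraries left out in turn for the lists. Replicate numbers were treated as unpaired, except that MUTEv5#5 and MUTE replicates of the same number resembled each other by the rule set for this (residual correlations of 0.57, 0.41 and 0.32); for that comparison the value with a replicate block is given too.

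The calling was tested on simulated data with the size of MUTEPPP#3 against MUTE, in which 200 of 22596 genes were changed. It recovered 12% of the genes changed 1.5-fold, 60% at 2-fold, 84% at 3-fold and 92% at 4-fold, and 6 of 130 calls were false. The changed genes were drawn from those above a minimum mean count. Many more genes were called in the real comparison, which makes its threshold less strict, so these shares are not its sensitivity. For 278 genes named or listed, the annotation was searched for overlapping genes and near copies: 6 overlap another gene on the same strand, 42 overlap a gene on the opposite strand, and 28 share at least 90% identity over at least 100 bp with another transcript. Counts of those genes can hold reads of the other gene. Not all of them are marked where they are named below. Among the unmarked, *SLAC1*, *ERL1*, *FLP*, *LUX*, *FKF1*, *COL2*, *CDKB2;2* and *CYCA2;3* overlap a gene on the opposite strand, and *CYCB2;3*, *KIN2* and *VSP2* have near copies.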

Results

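RNA from whole seedlings was counted in 4 lines of mute-3 plants that carry a *MUTE* transgene, with 3 libraries per line. MUTE line 1 makes the wild-type protein, MUTEv5#2 and MUTEv5#5 make the R10W protein, and MUTEPPP#3 makes a protein with proline at positions 3, 7 and 11. In the submitters' description, MUTEv5#2 forms moderately clustered stomata and MUTEv5#5 has many arrested lineages. Total counts of the 3 replicates were 150893904, 149323682 and 117868477 for MUTE and 127921202, 125291152 and 147047090 for MUTEv5#2. They were 149035238, 135741038 and 134469363 for MUTEv5#5 and 152600239, 132401313 and 144137913 for MUTEPPP#3. Each variant line was compared with MUTE to ask which transcripts differ when the MUTE protein is altered. The MUTEv5 lines were compared with each other to set a single allele at 2 strengths side by side, and MUTEPPP#3 with each MUTEv5 line to compare alleles. MUTE is represented by 1 line, so any difference that all variant lines share can also belong to that line. The MUTEPPP allele is represented by 1 line as well, so its effect cannot be told apart from that of the line or its insertion site.

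*MUTE* itself (AT3G06120, chromosome 3, 1846442 to 1848259, plus strand) was more abundant in both MUTEv5 lines than in MUTE, and its level in MUTEPPP#3 was close to that in MUTE. It stood at 5.31 ± 0.683 CPM (SD, n = 3) in MUTE, 10.7 ± 2.34 in MUTEv5#2, 18.6 ± 5.29 in MUTEv5#5 and 5.89 ± 0.899 in MUTEPPP#3. The log2 fold change over MUTE was 1.00 (SE 0.218, adjusted p = 0.0315) in MUTEv5#2, 1.81 (SE 0.222, adjusted p = 0.00403) in MUTEv5#5 and 0.15 (SE 0.217, adjusted p = 0.653) in MUTEPPP#3. *MUTE* was lower in MUTEPPP#3 than in MUTEv5#5 by a log2 fold change of -1.66 (adjusted p = 0.00194). Neither the contrast of the MUTEv5 lines (0.80, 95% interval 0.32 to 1.28, adjusted p = 0.259) nor that of MUTEPPP#3 with MUTEv5#2 (-0.86, adjusted p = 0.0648) passed the threshold. The counts join the transgene and the mute-3 locus and do not tell the alleles apart. The rise in MUTEv5#2 was not called without MUTE replicate 1, 2 or 3 or MUTEv5#2 replicate 1 or 2, where it ran from 0.84 to 1.12. With only the compared groups in the fit, the rise was called in neither MUTEv5 line. With the clock index as a covariate, *MUTE* was called higher in MUTEPPP#3 than in MUTE.

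**Figure D1:**
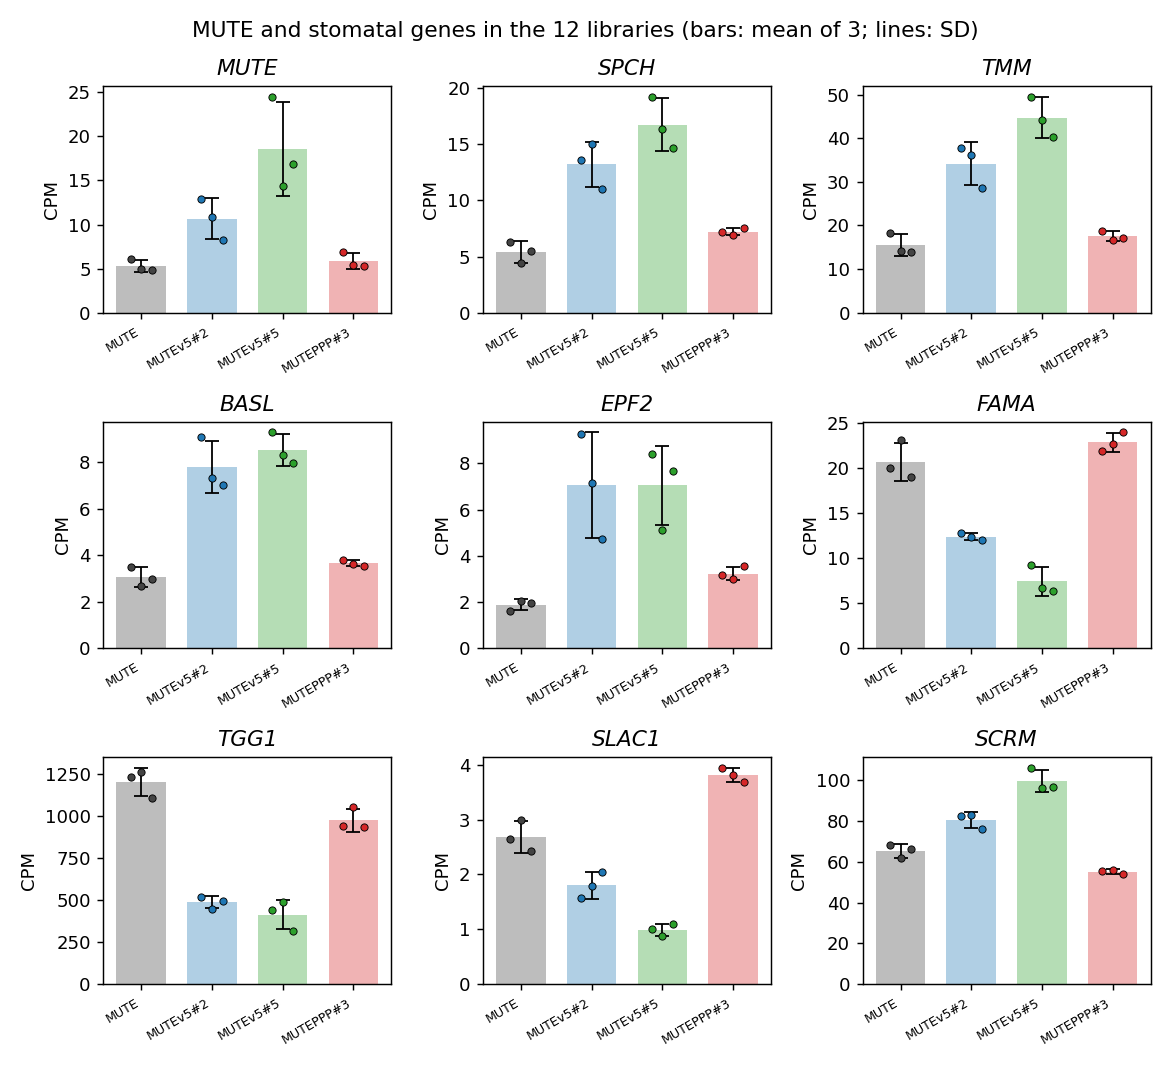
Normalised counts (CPM) of 9 stomatal genes in each of the 12 libraries, by line; bars are the mean of 3 libraries and lines the SD. *SPCH*, *TMM*, *BASL* and *EPF2* were higher and *FAMA* and *TGG1* lower in both MUTEv5 lines than in MUTE, and *MUTE* ran from 5.31 CPM in MUTE to 18.6 CPM in MUTEv5#5.

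In MUTEv5#2 against MUTE, 6 of 16 early stomatal lineage genes rose and 8 of 14 guard cell genes fell. With an estimated correlation between genes the guard cell list was called (adjusted p = 0.018) and the early lineage list was not (adjusted p = 0.27). *SPCH* (AT5G53210), the bHLH factor that starts the lineage, rose to 13.2 ± 2.03 CPM from 5.41 ± 0.979, a log2 fold change of 1.29 (SE 0.159, adjusted p = 0.00446). *BASL*, a polarity protein of asymmetric divisions, rose by 1.35 (adjusted p = 0.00131). *TMM*, a receptor-like protein that spaces stomata, rose by 1.14 (adjusted p = 0.00422), and *EPF2*, a secreted peptide that limits entry into the lineage, by 1.91 (adjusted p = 0.00600). *TGG1* (AT5G26000), a myrosinase abundant in guard cells, went from 1205 ± 84.1 to 488 ± 35.8 CPM, a log2 fold change of -1.30 (SE 0.147, adjusted p = 0.00274). *FAMA* (AT3G24140), the bHLH factor that drives guard cell formation, fell by 0.74 on the log2 scale (SE 0.135, adjusted p = 0.0202).

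Of 16 early lineage genes, 6 rose and 1 fell (8 and 1 adjusted over the list alone), with a median log2 fold change of 0.31 (list adjusted p = 4.1e-05; adjusted p = 0.27 with an estimated correlation). Besides the 4 above, the polarity gene *POLAR* rose by 0.58 and *SCRM*, the bHLH partner of SPCH, MUTE and FAMA, by 0.30 (adjusted p = 0.0448), and the protease gene *SDD1*, which restricts stomata, had a log2 fold change of -1.05. Of 14 guard cell genes, 8 fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -0.79 (list adjusted p = 6.5e-11; adjusted p = 0.018 with an estimated correlation). They included *TGG2* (-1.09), the anion channel genes *ALMT12* (-1.33) and *SLAC1* (-0.58), the potassium channel gene *KAT2* (-0.92), the kinase genes *BLUS1* (-1.39) and *HT1* (-0.89) and the Dof factor gene *SCAP1* (-0.90). *BLUS1* overlaps a gene on the same strand. In the guard mother cell list, *FAMA* was the single call among 16 members (1 rise and 1 fall adjusted over the list alone, list adjusted p = 0.37). *ERL1* (0.51, adjusted p = 0.0598), *CYCA2;3* (0.20) and *CDKB1;2* (0.28) of that list were not called. Among 15 signalling genes, *TMM* and *EPF2* rose, and *EPFL9*, the mesophyll peptide that promotes stomata, changed by -1.18 (adjusted p = 0.0197). Adjusted over the list alone 4 rose and 1 fell, and the list was not called (adjusted p = 0.33).

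Iron deficiency genes fell: 4 of 10 (10 adjusted over the list alone), median -1.30 (list adjusted p = 1.2e-07; adjusted p = 0.20 with an estimated correlation). They included the ferric reductase *FRO2* (-2.42), the transcription factor *BHLH38* (-2.67), the transporter *OPT3* (-0.69) and the ubiquitin ligase *BTS* (-0.57). The photosynthesis list was lower, with a median of -0.33 over 19 members (list adjusted p = 7.3e-06; adjusted p = 0.63 with an estimated correlation), though 0 members were called, also over the list alone. Its members *LHCB5* (-0.40), *LHCA3* (-0.40) and *RBCS3B* (-0.38) had adjusted p from 0.0598 to 0.0954. DNA replication was called higher (14 members, median 0.18, list adjusted p = 0.041; adjusted p = 0.88 with an estimated correlation) with 0 members called either way, and *CDT1A* (0.38), *PCNA1* (0.40) and *MCM4* (0.25) did not pass. Salicylic acid defence was called lower (5 members, median -0.44, list adjusted p = 0.016; adjusted p = 0.41 with an estimated correlation) with 0 members called (2 falls adjusted over the list alone). Its lowest p was that of *EDS1* (-0.41, adjusted p = 0.0700), ahead of *ICS1* (-0.44) and *WRKY70* (-0.76). The share of ribosomal and organelle reads was 3.13% ± 1.33 in MUTEv5#2 and 1.37% ± 0.690 in MUTE. With this share as a covariate, an alternative added after the data were seen, 99 genes were called, all among the 1140 given next, and *MUTE* (1.05), *FAMA* and *EPFL9* were not. The changes did not shrink: over the 1140 genes the median ratio of the log2 fold change with the share to that without it was 1.05. The sign was the same for 100% of them, and the median SE was 0.165 against 0.129. With so few calls made again, a part played by this share in MUTEv5#2 stays open.

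Among called genes of at least 1 CPM on average whose groups did not overlap, a limit that holds wherever the largest changes are named, the largest rise was that of AT3G01345, at 186 ± 17.3 CPM against 0.553 ± 0.458 (log2 fold change 8.38, SE 0.716, adjusted p = 4.71e-04). AT2G17850 (4.77), the noncoding AT2G06002 (4.01), AT4G33560 (2.92), the haemoglobin gene *HB1* (2.60) and AT4G04223 (2.59) followed. The largest falls within this limit were those of the retrotransposon *RE2* (-4.85, adjusted p = 2.88e-04), *APD3* (-3.52), AT5G35777 (-3.34), AT2G30766 (-3.32), *PP2-B13* (-2.55) and the Myb factor *RVE1* (-2.47). In all, 1140 genes were called, 336 higher and 804 lower, 267 of them by at least 2-fold, and 30.3% of tested genes had groups that did not overlap, against 10% by chance. This 10%, here and below, is the chance for a single gene. Genes move together, so the share over all genes can lie far from it without an effect of the line. With library totals as the only scaling, which raised the median of all genes by 0.126, 1001 rose and 400 fell. With DESeq2 1026 rose and 1622 fell, and far fewer genes were called with only the compared groups in the fit.

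The count was 196, 139 and 484 without MUTE replicate 1, 2 and 3, 96 and 78 without MUTEv5#2 replicate 1 and 2, 737 without MUTEv5#5 replicate 3 and 615 without MUTEPPP#3 replicate 2. *FAMA* (-0.66, the value closest to 0 where several libraries apply), *EPFL9* (-0.998), *HB1* (2.41), AT2G17850 (4.25), AT4G33560 (2.55) and *BHLH38* (-1.78) were not called without MUTE replicate 1 or 2 or MUTEv5#2 replicate 1 or 2. *BHLH38* was also lost without MUTEv5#2 replicate 3 or MUTEPPP#3 replicate 2. AT2G17850 was at 6.83 without MUTE replicate 3, AT3G01345 at 9.34 without MUTE replicate 1 and AT2G30766 at -3.97 without MUTEv5#2 replicate 2. Nor were *RVE1* (-2.32) and *OPT3* (-0.63) called without MUTEv5#2 replicate 1 or 2, *OPT3* without MUTE replicate 2, or *FRO2* (-1.91) without MUTEv5#2 replicate 1 or 2 or MUTE replicate 1 or 3. The DNA replication list was not called without MUTE replicate 1 (adjusted p = 0.11) or 3 (0.17), MUTEv5#2 replicate 1 (0.40) or MUTEv5#5 replicate 1 (0.056), and the salicylic acid list without MUTE replicate 3 (0.053).

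In MUTEv5#5 against MUTE, 6 of 16 early lineage genes rose and 7 of 14 guard cell genes fell. Here too the guard cell list was called with an estimated correlation (adjusted p = 0.011) and the early lineage list was not (adjusted p = 0.085). *SPCH* reached 16.8 ± 2.33 CPM (log2 fold change 1.63, SE 0.160, adjusted p = 8.03e-04) and *TMM* 44.7 ± 4.66 CPM (1.53, SE 0.141, adjusted p = 5.48e-04). *FAMA* was at 7.42 ± 1.60 CPM against 20.7 ± 2.13 in MUTE (-1.48, SE 0.137, adjusted p = 5.48e-04) and *TGG1* at 414 ± 88.6 CPM (-1.54, SE 0.148, adjusted p = 6.91e-04). *SDD1* had the smallest p among early lineage genes (-1.80, SE 0.149, adjusted p = 3.88e-04).

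Of 16 early lineage genes, 6 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.53 (list adjusted p = 1.2e-10; adjusted p = 0.085 with an estimated correlation). *EPF2* rose by 1.91, *BASL* by 1.48, *POLAR* by 1.09 and *SCRM* by 0.61. Of 14 guard cell genes, 7 fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -0.87 (list adjusted p = 1.2e-14; adjusted p = 0.011 with an estimated correlation). These were *TGG1*, *SLAC1* (-1.44), *ALMT12* (-1.46), *BLUS1* (-1.38), *SCAP1* (-1.05), *HT1* (-0.95) and *TGG2* (-0.81). In the guard mother cell list, *FAMA* fell and the receptor kinase gene *ERL1* rose by 0.73 (adjusted p = 0.0410); 3 rose and 1 fell adjusted over the list alone, and the list was not called (adjusted p = 0.073). *CYCA2;3* (0.29, adjusted p = 0.124) and *SOL1* (0.60, adjusted p = 0.127) did not pass. Of the signalling genes 3 rose, *ERL1*, *TMM* and *EPF2* (4 adjusted over the list alone, list adjusted p = 0.073), and the kinase gene *MKK5* (0.48, adjusted p = 0.0944) was next. The signalling list was called higher with fry (adjusted p = 0.022) and without MUTE replicate 2 (0.048) or MUTEv5#5 replicate 2 (0.033).

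Iron deficiency genes fell here too, 5 of 10 (10 adjusted over the list alone), with a median of -1.72 (list adjusted p = 6.5e-11; adjusted p = 0.10 with an estimated correlation). *IRT1*, the root iron transporter, had 50, 3 and 10 counts in MUTEv5#5 against 3898, 1518 and 2615 in MUTE (log2 fold change -7.14, SE 1.33, adjusted p = 0.0371). *FRO2* (-2.67), *BHLH38* (-3.24) and the iron signalling peptide genes *IMA1* (-1.84) and *IMA2* (-1.75) were also lower. Jasmonate and wounding genes were called lower (10 members, median -0.73, list adjusted p = 0.028; adjusted p = 0.88 with an estimated correlation), with *LOX2*, a lipoxygenase of jasmonate synthesis, as the single call (-1.82, adjusted p = 0.00301), also over the list alone. *VSP2* (-1.16) and *TCH3* (-0.81) were not called. The photosynthesis list had a median of -0.17 (list adjusted p = 0.015; adjusted p = 0.88 with an estimated correlation), with 0 of 19 members called, also over the list alone. *LHCB5* (-0.25), *LHCA3* (-0.24) and *LHCA1* (-0.36) had the smallest p.

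Within the limit of 1 CPM and no overlap, the largest rises were those of the LOB-domain gene *LBD26* (3.00, adjusted p = 1.23e-04), *QQS* (2.74) and AT4G04223 (2.65), followed by *EPF2*, *MUTE* and AT1G33930 (1.78). The largest falls after *IRT1* were those of *RE2* (-4.42), AT2G30766 (-3.06), AT2G14247 (-2.87), *FRO2* and the cytosolic fumarase *FUM2* (-2.66), which has a near copy. In all, 235 genes were called, 71 higher and 164 lower, 105 by at least 2-fold, and 20.6% of tested genes had groups that did not overlap, against 10% by chance. With a replicate block 217 genes were called, *QQS* (2.73), AT2G30766 (-3.06) and *FRO2* (-2.58) were not, and *VSP2* was (-1.22). With library totals as the only scaling, 63 rose and 66 fell, and with DESeq2 488 rose and 688 fell.

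The count was 60 and 62 without MUTE replicate 2 and 3 and 59 without MUTEv5#5 replicate 3. It was 101 to 156 without MUTE replicate 1, MUTEv5#2 replicate 1 or 2, MUTEv5#5 replicate 1 or 2 or MUTEPPP#3 replicate 2 or 3. *ERL1* (0.66, the value closest to 0 as above), *QQS* (2.49), *IRT1* (-6.66), *FRO2* (-2.18) and AT2G30766 (-2.48) were not called when any of 8 or 9 libraries was left out on its own, and *IRT1* was at -8.68 without MUTEv5#5 replicate 1. Nor were *IMA1* (-1.65) without any single MUTE library or MUTEv5#5 replicate 1, AT2G14247 (-2.56) without any single MUTEv5#5 library or MUTE replicate 1 or 3, *TGG2* (-0.75) without MUTE replicate 2 or MUTEv5#5 replicate 3, and *FUM2* (-2.58) without MUTEv5#5 replicate 1 or 3. The jasmonate and photosynthesis lists were not called without MUTE replicate 3 (adjusted p = 0.38 and 0.069) or MUTEv5#5 replicate 1 (0.23 and 0.27).

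**Figure D2:**
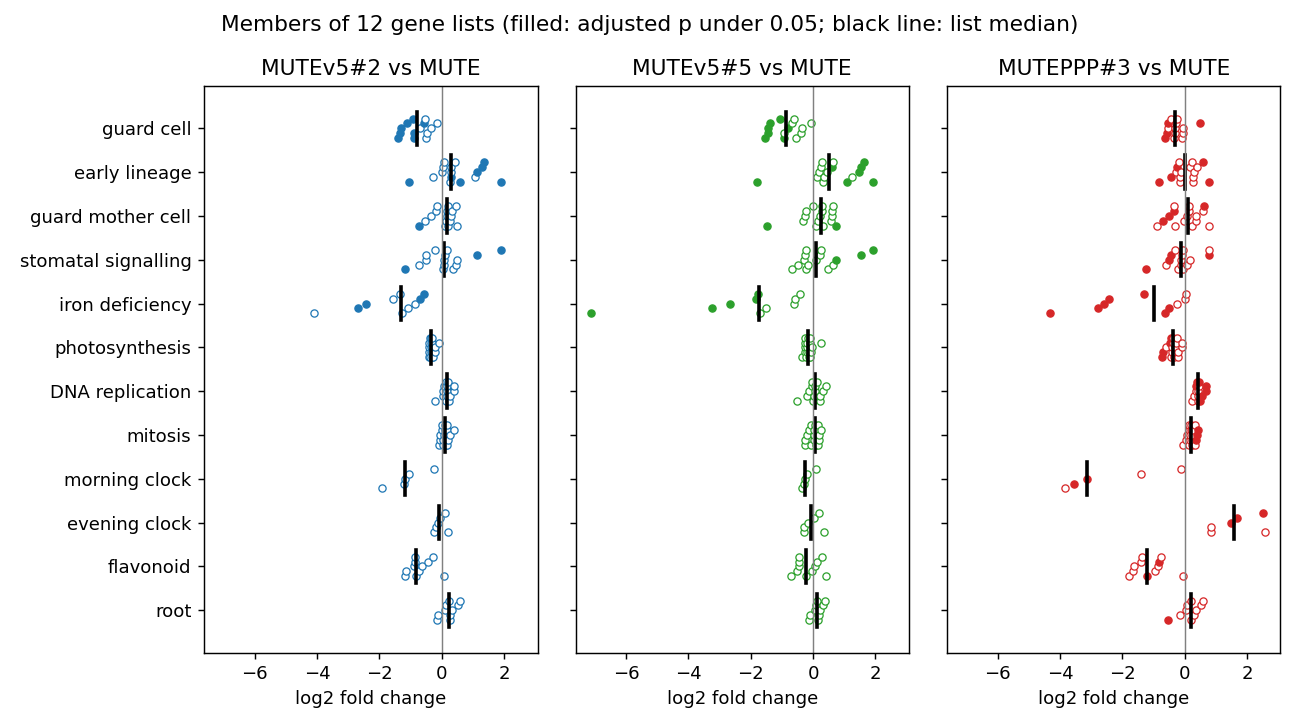
Log2 fold change against MUTE of the members of 12 gene lists in the 3 variant lines; filled points have an adjusted p under 0.05 and the black line is the list median. Guard cell genes had a median of -0.79 in MUTEv5#2, -0.87 in MUTEv5#5 and -0.31 in MUTEPPP#3, and early lineage genes 0.31, 0.53 and 0.03; under library totals as the only scaling the medians move with all genes, by up to 0.166.

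MUTEPPP#3 gave the most called genes of the 3 comparisons with MUTE, and *COR27* had the largest rise and *COPT2* the largest fall of at least 1 CPM on average without overlap between groups. *COR27*, an evening-expressed cold and clock gene, was at 33.7 ± 38.8 CPM against 0.442 ± 0.185 (log2 fold change 6.25, SE 1.32, adjusted p = 0.00774). With the clock index as a covariate, added after the data were seen, its log2 fold change was -0.022. *COPT2*, a copper transporter, was at 0.0892 ± 0.0504 CPM against 5.90 ± 2.38 (-6.02, SE 0.617, adjusted p = 4.21e-04), and *FRO4*, a metal reductase, changed by -5.67 (adjusted p = 9.05e-04). The stomatal regulators *SPCH* (0.41, adjusted p = 0.0786), *TMM* (0.18), *BASL* (0.26) and *FAMA* (0.14, adjusted p = 0.46) did not pass the test here.

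Among 16 early lineage genes 2 rose and 3 fell, also over the list alone, and the list was not called (adjusted p = 0.96). The cyclin gene *CYCD3;3* rose by 0.58 (adjusted p = 0.00225) and *EPF2* by 0.78 (adjusted p = 0.0406), while *SCRM* (-0.25), its paralog *SCRM2* (-0.81) and the receptor kinase gene *ERL2* (-0.45) fell. Of 14 guard cell genes, *SLAC1* rose by 0.50 (adjusted p = 0.0281), and *PATROL1* (-0.52), the kinase gene *OST1* (-0.57) and *ALMT12* (-0.64) fell, as they did over the list alone. The list median was -0.31 with 13 of 14 members lower, and it was not called (adjusted p = 0.061). It was called lower with fry (adjusted p = 0.011), a replicate block (0.039), library totals as the only scaling (0.047), and without MUTE replicate 3 (0.027) or MUTEv5#5 replicate 2 (0.048). In the guard mother cell list *CYCA2;1* rose by 0.61, and *ERL1* (-0.51), the Myb gene *FLP* (-0.69) and *SOL2* (-0.35) fell (4 rose and 3 fell adjusted over the list alone, list adjusted p = 0.83). Of the signalling genes *EPF2* rose and *EPFL9* (-1.23, adjusted p = 0.00337), *ERL1* and *ERL2* fell (2 and 3 adjusted over the list alone, list adjusted p = 0.41). With library totals as the only scaling *ERL1*, *ERL2*, *SCRM* and *SOL2* were not called.

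Evening clock genes rose: *LUX* (1.67), *ELF4* (2.52) and *TOC1* (1.49) of 6 (4 adjusted over the list alone), median 1.58 (list adjusted p = 0.028; adjusted p = 0.88 with an estimated correlation). With library totals as the only scaling this list was not called (adjusted p = 0.084), nor with fry (0.15). The morning list had a median of -3.12 and was not called (adjusted p = 0.068), though its members *CCA1* (-3.54, adjusted p = 0.00674) and *RVE8* (-3.12) fell (3 adjusted over the list alone). The clock index of the libraries, morning minus evening genes, was 3.35, 0.73 and 1.21 in MUTE and -0.09, -2.80 and -3.98 in MUTEPPP#3. With this index as a covariate, an alternative added after the data were seen, 2678 genes were called, and the DNA replication, mitosis, flavonoid and iron lists were not. The evening list was not called either, but its genes are part of the index, so this says nothing about them. DNA replication genes rose, 7 of 14 (12 adjusted over the list alone), median 0.43 (list adjusted p = 1.1e-04; adjusted p = 0.87 with an estimated correlation). The replication clamp genes *PCNA1* (0.70) and *PCNA2* (0.57) and the licensing factor *CDT1A* (0.48) had the smallest p. Of 19 mitosis genes 3 rose (0 adjusted over the list alone), *CYCB2;1* (0.40), *CYCB2;3* (0.42) and *CDKB2;2* (0.38), median 0.20 (list adjusted p = 0.015; adjusted p = 0.88 with an estimated correlation).

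Photosynthesis genes fell, 4 of 19 (12 adjusted over the list alone), median -0.36 (list adjusted p = 3.6e-04; adjusted p = 0.87 with an estimated correlation). These were the antenna genes *LHCB2.1* (-0.73) and *LHCB2.2* (-0.69) and the Rubisco subunit genes *RBCS3B* (-0.47) and *RBCS1B* (-0.43), all of which have near copies. Iron deficiency genes fell, 7 of 10 (7 adjusted over the list alone), median -0.97 (list adjusted p = 0.0053; adjusted p = 0.59 with an estimated correlation), among them *IRT1* (-4.33), *BHLH101* (-2.44), *FRO2* (-2.58) and *BTS* (-0.64). Flavonoid genes were called lower (2 of 11, 8 adjusted over the list alone, median -1.20, list adjusted p = 0.049; adjusted p = 0.88 with an estimated correlation). The members *F3'H* (-0.82) and the anthocyanin transport gene *GSTF12* (-1.20) fell, neither of them called with library totals as the only scaling, and their regulator *PAP1* (-1.38, adjusted p = 0.0504) did not pass.

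Further large rises were those of *FKF1*, a blue-light receptor of the flowering pathway (4.61), AT4G33980 (4.46), the receptor-like gene *RLP33* (4.22), AT2G17850 (4.13) and AT1G17665 (4.04). Of these, *FKF1* was at -0.64 and AT4G33980 at -0.60 with the clock index as a covariate. Further large falls were those of AT2G15020 (-5.54), the heat shock factor gene *HSFA6A* (-5.14), AT5G35777 (-4.64) and the CONSTANS-like gene *COL2* (-4.47). In all, 5577 genes were called, 2428 higher and 3149 lower, 1365 by at least 2-fold, and 40.7% of tested genes had groups that did not overlap, against 10% by chance. With library totals as the only scaling, which raised the median of all genes by 0.166, 4789 rose and 1862 fell.

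The count was 2995 without MUTEPPP#3 replicate 2. Without MUTEPPP#3 replicate 3, *COR27* (4.80), AT4G33980 (3.10) and AT1G17665 (2.95) were smaller. In the same setting *FKF1* (3.84), *ELF4* (1.44), *TOC1* (0.87) and the evening clock (adjusted p = 0.084), mitosis (0.14) and flavonoid (0.12) lists were not called, and without MUTEPPP#3 replicate 2 *RLP33* was at 3.304. Larger changes were seen for AT2G17850 (6.20 without MUTE replicate 3), *FKF1* (5.41 without MUTE replicate 2), AT5G35777 (-5.39 without MUTEPPP#3 replicate 3), and AT2G15020 (-6.77) and *COL2* (-5.45) without MUTEPPP#3 replicate 1. Without MUTE replicate 1, these 3 lists (0.092, 0.051 and 0.41), *GSTF12* (-0.52), *F3'H* (-0.37), *SLAC1*, *ALMT12*, *SCRM*, *ERL1*, *FLP*, *CYCA2;1*, *SOL2*, *EPF2* and the 3 mitosis genes were not called, *HSFA6A* was at -4.32 and *COL2* at -3.08. These losses were not tied to that library alone: of the 12 libraries left out in turn, 11 ended the call of *SOL2*, 10 that of *GSTF12*, 9 that of *TOC1* and 8 that of *CYCB2;1*. The number was 7 for *SCRM* and *EPF2*, 5 for *SLAC1* and *FKF1*, 4 for *F3'H*, *ERL1*, *CYCA2;1*, *CYCB2;3* and *CDKB2;2*, 3 for *ELF4*, and 2 for *ALMT12* and *FLP*. The flavonoid list was also not called without MUTEv5#2 replicate 3 (0.054), MUTEv5#5 replicate 1 (0.065) or MUTEPPP#3 replicate 1 (0.058).

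**Figure D3:**
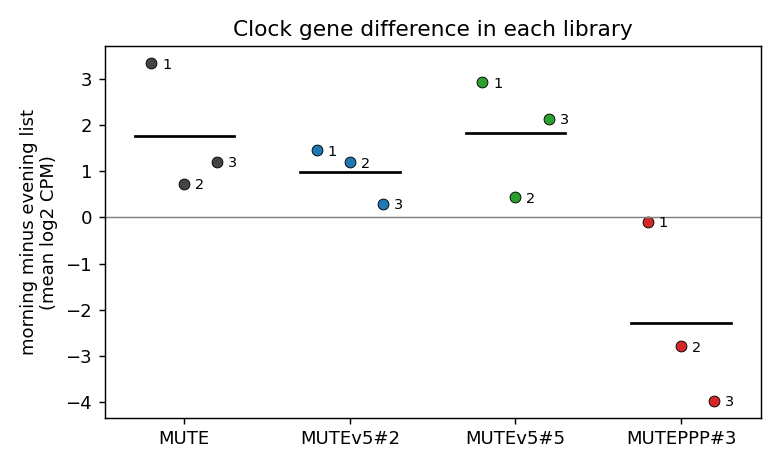
Clock index of each of the 12 libraries, the mean log2 CPM of the morning clock list minus that of the evening list, with the group mean as a bar. The 3 MUTEPPP#3 libraries, at -0.09, -2.80 and -3.98, lie below all 9 others, which run from 0.30 to 3.35.

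MUTEv5#5 and MUTEv5#2 carry the same allele, and few genes passed the test between them. AT3G01345 (-7.37, SE 0.680, adjusted p = 0.00271), the noncoding AT2G06002 (-3.64, adjusted p = 0.00217) and AT5G26270 (-1.66, SE 0.114, adjusted p = 3.76e-04) were lower in MUTEv5#5. *LBD26* (1.62, adjusted p = 0.0109), *PUT1* (1.34) and AT1G23052 (1.16) were higher. Of the stomatal genes, *FAMA* (-0.74, adjusted p = 0.12), *SLAC1* (-0.87, adjusted p = 0.096), *SDD1* (-0.74, adjusted p = 0.12) and *SPCH* (0.34, adjusted p = 0.46) did not pass. The early lineage list was called higher in MUTEv5#5 (median 0.18, list adjusted p = 0.015; adjusted p = 0.59 with an estimated correlation) with 0 members called (2 higher and 1 lower adjusted over the list alone). Photosynthesis (0.16, list adjusted p = 0.0013; adjusted p = 0.87 with an estimated correlation) and flavonoid genes (0.55, list adjusted p = 0.049; adjusted p = 0.88 with an estimated correlation) were also called higher, with 0 members called, also over the list alone. The other stomatal lists were not called, with adjusted p = 0.58 for guard cells, 0.65 for the guard mother cell step and 0.21 for signalling. In all, 15 genes were called, 4 higher and 11 lower, and DESeq2 called 300 (191 higher and 109 lower). An unadjusted p under 0.05 in edgeR was found for 2455 genes (1132 by chance), and 18% of tested genes had groups that did not overlap, against 10% by chance. The count was 35 without MUTE replicate 1, 3 and 5 without MUTEv5#2 replicate 1 and 2, and 5 and 5 without MUTEv5#5 replicate 2 and 3. *LBD26* (1.57) and AT1G23052 (1.05) were not called without MUTEv5#2 replicate 1 or 2 or MUTEv5#5 replicate 3, nor AT1G23052 without MUTEv5#5 replicate 2, nor was *PUT1* (1.14) when any of 10 libraries was left out on its own. The early lineage list was not called without MUTEv5#2 replicate 3 (adjusted p = 0.23) or MUTEv5#5 replicate 1 (0.10), photosynthesis without MUTEv5#5 replicate 2 (0.057), and flavonoids when any of 7 libraries was left out on its own (0.052 to 0.21).

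Tested directly, 7 of 14 guard cell genes were higher in MUTEPPP#3 than in either MUTEv5 line, and 7 and 10 of 16 early lineage genes were lower than in MUTEv5#2 and MUTEv5#5. None of these 4 list calls was made with an estimated correlation (adjusted p = 0.085 and 0.13 for guard cells, 0.27 in both for the early lineage). *FAMA* was higher by 0.89 than in MUTEv5#2 (adjusted p = 0.013) and by 1.62 than in MUTEv5#5 (adjusted p = 7.1e-04), and *SLAC1* by 1.08 (adjusted p = 0.0091) and 1.95 (adjusted p = 7.1e-04). *SPCH* was at -0.88 (adjusted p = 0.023) and -1.22 (adjusted p = 0.0017), *BASL* at -1.09 and -1.22, and *TMM* at -0.96 and -1.35. Of 14 guard cell genes 7 were higher and 1 lower, *PATROL1*, in each comparison (8 and 1 adjusted over the list alone). The medians were 0.68 against MUTEv5#2 (list adjusted p = 1.2e-05; adjusted p = 0.085 with an estimated correlation) and 0.57 against MUTEv5#5 (list adjusted p = 2.3e-04; adjusted p = 0.13 with an estimated correlation). Of 16 early lineage genes 7 were lower and 1 higher, *SDD1*, against MUTEv5#2 (11 and 2 adjusted over the list alone; median -0.53, list adjusted p = 3.2e-05). Against MUTEv5#5 these were 10 and 1 (12 and 2 adjusted over the list alone; median -0.77, list adjusted p = 2.6e-05). Both early lineage results had an adjusted p = 0.27 with an estimated correlation. Signalling genes were called lower against both, 4 and 5 of 15 (5 and 6 adjusted over the list alone), medians -0.19 and -0.15 (list adjusted p = 0.021 and 0.015; adjusted p = 0.45 and 0.41 with an estimated correlation). *ERL1* was at -1.02 and -1.24. The guard mother cell list was not called (adjusted p = 0.81 and 0.54).

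Among the other lists, DNA replication genes were called higher in MUTEPPP#3 than in MUTEv5#2 and MUTEv5#5 (medians 0.26 and 0.38, list adjusted p = 8.5e-04 and 2.8e-04). So were evening clock genes (1.57 and 1.65, list adjusted p = 0.0034 and 0.0085) and cold and abscisic acid genes (1.26 and 1.51, list adjusted p = 0.015 in both). With an estimated correlation their adjusted p = 0.87 in both comparisons for DNA replication and cold genes, and 0.78 and 0.87 for evening genes. Members called were 0 and 2 of 14 for DNA replication (0 and 11 adjusted over the list alone), 1 and 3 of 6 for evening genes (4 and 4), and 0 and 4 of 11 for cold genes (5 and 7). Against MUTEv5#5 the cold genes included *RD29A* (3.96) and *DREB1A* (4.08). Against MUTEv5#5 alone, mitosis genes were called higher (2 of 19, 1 adjusted over the list alone; median 0.18, list adjusted p = 0.026; adjusted p = 0.88 with an estimated correlation). Called lower there were flavonoid (0 of 11 either way; -1.07, list adjusted p = 0.026; adjusted p = 0.88 with an estimated correlation) and photosynthesis genes (3 of 19, also over the list alone; -0.14, list adjusted p = 0.041; adjusted p = 0.88 with an estimated correlation). Within the same limit, the largest rises were those of *COR27* (6.42 and 6.45), AT1G17665 (3.78) and the clock gene *PRR3* (3.51) over MUTEv5#2, and of the cold gene *COR15A* (5.75) and AT4G33980 (4.98) over MUTEv5#5. The largest falls were those of *COPT2* (-5.77 and -5.10), *FRO4* (-5.51 and -4.92), AT3G01345 (-6.69) against MUTEv5#2 and AT2G15020 (-5.97) against MUTEv5#5.

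In all, 558 genes were called against MUTEv5#2 (241 higher, 317 lower) and 3553 against MUTEv5#5 (1430 higher, 2123 lower), with 27.2% and 33.3% of tested genes without overlap between groups, against 10% by chance. With library totals as the only scaling 205 were higher and 191 lower against MUTEv5#2, and 2004 and 1445 against MUTEv5#5. With DESeq2 these were 1088 and 1036, and 2365 and 2724. Against MUTEv5#2 the count was 983, 297 and 274 without MUTE replicate 1, 2 and 3, 102, 82 and 126 without MUTEv5#2 replicate 1, 2 and 3, 297 without MUTEv5#5 replicate 3, and 1904, 40 and 104 without MUTEPPP#3 replicate 1, 2 and 3. *COR27*, AT1G17665 and *PRR3*, at 4.97, 2.70 and 2.81 without MUTEPPP#3 replicate 3, were not called when any of 8 to 10 libraries was left out on its own, nor was *FRO4* without MUTEPPP#3 replicate 2. Against MUTEv5#5 it was 2313, 2336 and 1596 without MUTEv5#5 replicate 1, 2 and 3 and 1061 and 1986 without MUTEPPP#3 replicate 2 and 3, and *COR15A* (3.47) was not called without MUTEPPP#3 replicate 2 or MUTEv5#5 replicate 1 or 3. AT2G15020 was at -4.25 without MUTEv5#5 replicate 2 and *FRO4* at -4.03 without MUTEv5#5 replicate 1, and *COR27* and AT4G33980 were at 4.99 and 3.62 without MUTEPPP#3 replicate 3. They were at 7.14 and 5.62 without MUTEv5#5 replicate 2, AT2G15020 at -7.20 without MUTEPPP#3 replicate 1, and *COR27* against MUTEv5#2 at 7.09 without MUTEv5#2 replicate 3. *COR27* was not called without MUTEv5#5 replicate 3, nor AT4G33980 without MUTEv5#5 replicate 1 or 3. Of the lists against MUTEv5#2, cold genes were not called without MUTEPPP#3 replicate 1 (adjusted p = 0.086) or 2 (0.095), nor signalling without MUTEPPP#3 replicate 1 (0.051). Against MUTEv5#5, cold genes were not called without MUTEv5#5 replicate 1 (0.065) or MUTEPPP#3 replicate 1 (0.068), mitosis without MUTEv5#5 replicate 1 (0.14) or MUTEPPP#3 replicate 3 (0.24), flavonoids without MUTEv5#5 replicate 1 (0.075) or 3 (0.063) or MUTEPPP#3 replicate 3 (0.089), and photosynthesis without MUTEv5#5 replicate 2 (0.17) or 3 (0.10) or MUTEPPP#3 replicate 3 (0.22).

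Across the 3 comparisons with MUTE, a set of 98 genes was called in the same direction in all variant lines, 27 higher and 71 lower, where independent lists of these sizes would share 0.113 and 0.810. Chosen as the 5 for which the largest of the 3 p-values was lowest, the shared rises to name are those of AT4G04223 (2.59, 2.65 and 3.67 in MUTEv5#2, MUTEv5#5 and MUTEPPP#3) and AT5G38005 (1.92, 1.59 and 2.47), which share sequence with each other. The others are AT4G15390 (0.80, 0.82 and 0.67), the ascorbate-recycling reductase gene *ATMDAR2* (2.24, 1.40 and 2.14) and *LBD26* (1.37, 3.00 and 1.82). The shared falls chosen in this way are those of AT1G27565 (-4.11, -3.71 and -4.17), *RE2* (-4.85, -4.42 and -3.85), *APD3* (-3.52, -2.36 and -3.16) and the callose-binding gene *PDCB3* (-0.61, -0.52 and -0.67); AT1G27565 and *APD3* have near copies. In MUTEv5#5, *PDCB3* (-0.51) was not called without MUTE replicate 2, nor *APD3* (-2.12) without MUTEv5#5 replicate 3. The fifth, the microRNA gene *MIR5642b*, which also has near copies, had 33, 25 and 12 counts in MUTE and 2 in each of the 9 variant libraries. MUTEv5#2 and MUTEv5#5 shared 47 rises and 114 falls, where independent lists would share 1.05 and 5.83. MUTEv5#2 and MUTEPPP#3 shared 229 and 614 (36.0 and 112 if independent), and MUTEv5#5 and MUTEPPP#3 32 and 100 (7.62 and 22.8). The correlations of log2 fold changes over all genes were 0.64, 0.67 and 0.40 for these pairs, against a mean of 0.50 in data simulated with no effect. There the comparisons share 3 simulated MUTE libraries. Each gene was drawn on its own, so coordinated differences among the real MUTE libraries are absent from the simulated values. The covariances were 0.105, 0.184 and 0.0918 against 0.0430, 0.0426 and 0.0430. The 3 MUTE libraries are too few to be divided between the comparisons, so part of the overlap can come from them. The shared set had 24, 14 and 21 genes without MUTE replicate 1, 2 and 3, 21 and 21 without MUTEv5#2 replicate 1 and 2, 25 and 21 without MUTEv5#5 replicate 1 and 3, and 31 and 47 without MUTEPPP#3 replicate 2 and 3.

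The remaining lists were not called in any of the 6 comparisons with the preset correlation and TMM scaling. Their lowest adjusted p was 0.41 for auxin response, 0.062 for cytokinin response, 0.14 for root cell types (each in MUTEv5#2 against MUTE). It was 0.37 for seed storage and maturation (MUTEv5#5 against MUTE), 0.26 for epidermis and cuticle (MUTEv5#5 against MUTEv5#2) and 0.69 for trichome and hair patterning (MUTEPPP#3 against MUTEv5#2). It was 0.061, 0.21 and 0.88 for morning clock genes, heat shock and lipid reserve mobilisation (MUTEPPP#3 against MUTEv5#5). The seed list had 4 of 16 genes in the table. Some of these lists were called under an alternative. Morning clock genes in MUTEPPP#3 against MUTE were called with fry (adjusted p = 0.0036), a replicate block (0.031), library totals (0.011) and without MUTE replicate 1 (0.048) or MUTEPPP#3 replicate 1 (0.029), and they were called with fry, the block and library totals against both MUTEv5 lines too. Auxin response was called in MUTEPPP#3 with the clock index as a covariate against MUTE (0.023), MUTEv5#2 (5.6e-05) and MUTEv5#5 (2.7e-04), and without MUTEPPP#3 replicate 3 against MUTEv5#2 (4.3e-04) and MUTEv5#5 (0.023). Cytokinin response was called in MUTEv5#2 against MUTE with library totals (0.012), a replicate block (0.039) and without MUTEv5#2 replicate 3 (0.0020) or MUTEv5#5 replicate 2 (0.044), and in MUTEPPP#3 against MUTE with library totals (0.028). It was also called between the MUTEv5 lines without MUTEv5#2 replicate 3 (0.0026) or MUTEv5#5 replicate 2 (0.028). Heat shock was called with a replicate block in MUTEPPP#3 against MUTEv5#2 (0.046) and MUTEv5#5 (0.026). The root list was called in MUTEv5#2 without MUTEv5#2 replicate 1 (0.048) and in MUTEv5#5 without MUTEv5#5 replicate 1 (0.010), each against MUTE. Single members were called all the same, such as the type-A response regulator gene *ARR9* (-0.96 in MUTEv5#2 and -1.21 in MUTEPPP#3) and, in MUTEPPP#3, the hair patterning gene *TRY* (-2.25) and the root gene *SCR* (-0.53).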

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

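Naming the genes with opposite changes, adding the clock index and the share of ribosomal reads as covariates, the sizes of the changes under these covariates, and the tests of the root list, of clock phase for the iron list by line, of *MUTE* against the early lineage list and of copy number were chosen after the results were seen.

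Genes that changed in opposite directions against MUTE in 2 variant lines, with the direct contrast of the lines also past the threshold, drew attention as a difference between groups. For MUTEv5#2 and MUTEPPP#3 there were 4: *SLAC1* (-0.58 and 0.50, direct log2 fold change 1.08), *SCRM* (0.30 and -0.25, direct -0.54), *WRKY49* (-1.21 and 0.78, direct 2.00) and AT1G23200 (-1.06 and 1.03, direct 2.09), with direct adjusted p from 0.00633 to 0.00914. For MUTEv5#5 and MUTEPPP#3 there were 7: *SLAC1* (-1.44 and 0.50, direct 1.95), *SCRM* (0.61 and -0.25, direct -0.85), *ERL1* (0.73 and -0.51, direct -1.24), AT1G23200 (-2.07 and 1.03, direct 3.10), AT2G39690 (-0.72 and 0.43, direct 1.15), AT4G25620 (0.70 and -0.43, direct -1.13) and AT5G44580 (0.96 and -0.56, direct -1.52), with direct adjusted p from 7.06e-04 to 0.00136. The adjusted p against MUTE ran from 0.00106 to 0.0478, both for *SLAC1*, in MUTEv5#5 and MUTEv5#2. The calls of *SCRM* and *ERL1* in MUTEPPP#3 against MUTE ended with library totals as the only scaling. With libraries left out in turn, 7 ended the call of *SCRM* and 5 that of *SLAC1* in MUTEPPP#3, and 8 that of *ERL1* in MUTEv5#5. The calls of *SLAC1* and *SCRM* in MUTEv5#2 and the direct contrasts of these genes were not followed under the alternatives. Nor were *WRKY49*, AT1G23200, AT2G39690, AT4G25620 and AT5G44580, so how far these calls hold is not known. A direct contrast shows that the lines differ, not that each moved away from MUTE.

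MUTEPPP#3 differed from MUTE in 5577 genes, and its 3 libraries had a clock index of -0.09, -2.80 and -3.98, below the 9 others. A different share of ribosomal and organelle reads is argued against as the cause in MUTEPPP#3. With that share as a covariate, 84.6% of the calls were made again in the same direction. With the clock index as a covariate, 29.7% of the calls were made again, but the changes mostly stayed in size: over the 5577 genes the median ratio of the log2 fold change with the index to that without it was 0.893, 98.0% had the same sign, and the median standard error was 0.203 against 0.141. Collection at another clock phase may account for a part, since 19.2% of these genes fell below 0.5 of their log2 fold change, such as the evening-expressed *COR27* (6.25 to -0.022). The index follows the group, so the covariate also takes up any effect of the allele or of the single MUTEPPP line. The explanations cannot be told apart, and the hour of collection is not given in the sources used here.

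The iron deficiency list was called lower in all variant lines than in MUTE, with medians of -1.30, -1.72 and -0.97 for MUTEv5#2, MUTEv5#5 and MUTEPPP#3, though in none with an estimated correlation (adjusted p = 0.20, 0.10 and 0.59), and *IMA1* (0.06) and *IMA2* (2e-04) were not lower in MUTEPPP#3. A single deviating MUTE library is argued against, since the highest of 9 medians with 1 MUTE library left out was -0.82, and so is a smaller share of root, since the root list had no median below 0.14 (SD over its members 0.16 to 0.33). Clock phase is argued against as the whole cause in the MUTEv5 lines, where with the index as a covariate the medians were -1.24 and -1.75 and the list was still called (adjusted p = 2.99e-06 and 6.53e-10). In MUTEPPP#3 the median was -0.89 with the index (SD over members 1.18, against 1.48 without it). The median standard error of the members was 0.53 against 0.34 and the list was not called (adjusted p = 0.22). Phase cannot be told apart there from allele or line, as the index follows the group. A feature of the single MUTE line or of its growth stays open as a possible explanation and was not tested.

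The *MUTE* transcript was higher than in MUTE by 1.00 in MUTEv5#2 and 1.81 in MUTEv5#5. More cells held in an early lineage state would raise it together with the other genes of that state. The median of the whole early lineage list was 0.31 and 0.53 (SD over 16 members 0.72 and 0.88), at differences of -0.70 and -1.28 from *MUTE*. This is within the SD in 1 line and beyond it in the other. The members did not move together: in each line 6 rose, 1 (*SDD1*) fell and 9 were not called. *SPCH*, *BASL*, *TMM* and *EPF2* rose by more than the median in both lines, and by more than *MUTE* in MUTEv5#2. The median can therefore understate a rise in early cells, and this explanation stays open. Transgene copy number or insertion site may add to the rise of *MUTE*, since the lines of this allele differed by 0.80 (95% interval 0.32 to 1.28, adjusted p = 0.259). Copy number cannot be told apart from the strength of the phenotype, because the counts carry no measure of transgene copies and each strength is a single line.

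Other groupings were examined by splitting the 6 libraries of each comparison into 3 and 3 in all 10 ways. In each comparison 1 split, the real one, gave as many called genes, and 10 splits are too few for a share under 0.05. The real count and the highest other were 1140 and 0 for MUTEv5#2, 235 and 216 for MUTEv5#5 and 5577 and 0 for MUTEPPP#3 against MUTE, 15 and 0 for MUTEv5#5 against MUTEv5#2, and 558 and 0 and 3553 and 0 for MUTEPPP#3 against MUTEv5#2 and MUTEv5#5. The split with 216 sets MUTE replicate 1 and MUTEv5#5 replicates 1 and 3, the 3 of these 6 libraries with the highest clock index (3.35, 2.93 and 2.14), against the rest, which points to a structure among these libraries besides the lines. The real split parts all 3 pairs of like replicate number and this one does not; the other splits that part all 3 pairs gave 0, and with a replicate block the real count was 217.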

How the results depend on the processing

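The clock index and ribosomal share covariates, the omission of the 2 libraries with the highest clock index and the libraries left out for the lists were chosen after seeing the data. Unless a setting has fewer libraries, the cause of a difference was not tested. Over the 157 values of named genes and 3608 alternatives, 3140 kept their direction and side of the threshold, 427 kept the direction but were no longer called, 34 became called and 7 reversed. The reversals came with the clock index as a covariate: against MUTE in MUTEPPP#3 *COR27* went to -0.022, *FKF1* to -0.64, AT4G33980 to -0.60, *ELF4* to -0.47, *TOC1* to -0.64 and *GSTF12* to 0.15, and AT4G33980 went to -0.28 against MUTEv5#5. Counts of called genes stayed within 1.5 times the value given with limma-voom, RLE scaling, a replicate block (1245, 217, 6162, 15, 810 and 4030) and both other filters in all 6 comparisons. For MUTEv5#2 against MUTE the count was 2648 with DESeq2, 171 with only the compared groups in the fit, 2422 with the clock index, 99 with the ribosomal share, 411 without the 2 libraries, and 78 to 1399 with 1 library left out. For MUTEv5#5 against MUTE it was 1176 with DESeq2, 129 with library totals, 42 with only the compared groups, 588 with the clock index, 62 with the ribosomal share, 67 without the 2 libraries, and 59 to 274 with 1 left out. For MUTEPPP#3 against MUTE it was 3231 with only the compared groups, 2678 with the clock index, and 2995 to 5666 with 1 left out. For MUTEv5#5 against MUTEv5#2 it was 300 with DESeq2, 34 without the 2 libraries, and 3 to 35 with 1 left out. For MUTEPPP#3 against MUTEv5#2 it was 2124 with DESeq2, 129 with only the compared groups, 84 with the clock index, 72 with the ribosomal share, 1141 without the 2 libraries, and 40 to 1904 with 1 left out. Against MUTEv5#5 it was 1894 with only the compared groups, 625 with the clock index, and 1061 to 4423 with 1 left out. Where the ribosomal share lowered the count against MUTE, the called changes kept their size. The median ratio of the log2 fold change with the share to that without it was 1.05 in MUTEv5#2 and 1.00 in MUTEv5#5. The sign was the same for 100% of them. Genes changed at least 2-fold numbered 476 with DESeq2 and 65 to 322 with 1 library left out in MUTEv5#2 (267 given), 219 with DESeq2 and 46 to 104 in MUTEv5#5 (105 given), and 885 to 1578 with 1 left out in MUTEPPP#3 (1365 given). A test against a fold of 1.2, which counts genes past 1.2-fold and so measures another quantity, gave 106, 72 and 2391. The set shared by all 3 comparisons had 461 genes with DESeq2 and 14 to 92 with 1 library left out. DESeq2 made 1137 of the 1140, 234 of the 235 and 5569 of the 5577 calls against MUTE again. The *MUTE* log2 fold change in MUTEv5#2 was not called with only the compared groups (1.01) or the ribosomal share (1.05) and ran from 0.84 to 1.16 with 1 library left out. In MUTEv5#5 it was not called with only the compared groups (1.81) and ran from 1.55 to 1.95. In MUTEPPP#3 it was called with the clock index (0.82) and ran from 0.02 to 0.29. With an estimated correlation 1, 1, 0, 0, 0 and 0 lists were called in the 6 comparisons in the order above. By the fry test, the lists called were 0 for MUTEv5#5 against MUTEv5#2 and 4 for MUTEPPP#3 against MUTEv5#5. With the clock index as a covariate 5 were called in the last comparison, of which cold, early lineage and guard cell genes were called without it and auxin (adjusted p = 2.7e-04) and iron (0.033) were not. The index is built from the clock lists, so its effect on them and on *ELF4* and *TOC1* says nothing about those genes. Fry did not call DNA replication, evening clock, mitosis, cold and jasmonate genes or flavonoids in any comparison, nor photosynthesis except in MUTEPPP#3 against MUTE. Other lists not called were called under an alternative. In MUTEv5#2 against MUTE these were jasmonate (adjusted p = 0.046 with a block, 0.025 with library totals, 0.0098 and 0.024 without MUTE replicate 1 and MUTEv5#2 replicate 3), mitosis (0.047 with a block, 0.037 with library totals, 0.0032 without MUTEv5#2 replicate 1) and flavonoids (0.028 with library totals, 0.017 and 0.023 without MUTE replicate 2 and 3). In MUTEv5#5 against MUTE they were salicylic acid (0.047 with library totals, 0.024 without MUTE replicate 1), cold (0.029 with library totals) and flavonoids (0.0098 without MUTE replicate 1), and in MUTEPPP#3 against MUTE jasmonate (0.023 with the clock index, 0.037 without MUTE replicate 1). Between the MUTEv5 lines they were mitosis (0.0033 without MUTEv5#2 replicate 1) and DNA replication (0.0033 without MUTEv5#2 replicate 3). In MUTEPPP#3 against MUTEv5#2 they were mitosis (0.024 with a block, 0.029 with library totals, 0.044 with the clock index, 6.8e-04 and 0.0074 without MUTEv5#2 replicate 3 and MUTEPPP#3 replicate 1), and with the clock index flavonoids (0.049) and iron (0.044). List calls that ended with the clock index, besides those given for MUTEPPP#3 against MUTE, were DNA replication in MUTEv5#2 against MUTE (0.20), flavonoids between the MUTEv5 lines (0.34), DNA replication (0.34) and signalling (0.20) in MUTEPPP#3 against MUTEv5#2, and DNA replication (0.26), flavonoids (0.33), mitosis (0.14), photosynthesis (0.059) and signalling (0.14) against MUTEv5#5. With library totals DNA replication in MUTEv5#2 against MUTE was not called (0.058), nor with a block photosynthesis in MUTEPPP#3 against MUTEv5#5 (0.050). With 1 library left out the numbers ran from 5 to 8, 3 to 7, 4 to 7, 1 to 3, 5 to 7 and 6 to 10. Further named genes lost a call with 1 library left out. In MUTEv5#2 against MUTE these were AT2G30766 (-2.74, MUTE or MUTEv5#2 replicate 1), *PP2-B13* (-2.28, 7 libraries) and *BLUS1* (-1.30, MUTEv5#2 replicate 2). In MUTEv5#5 against MUTE they were *PDCB3* (-0.51, MUTE replicate 2) and *APD3* (-2.12, MUTEv5#5 replicate 3). In MUTEPPP#3 against MUTE they were *SCRM2* (-0.72, MUTEPPP#3 replicate 2), *LHCB2.1* (-0.56), *LHCB2.2* (-0.64) and *RBCS3B* (-0.40) (each without MUTE replicate 2 or 3 or MUTEPPP#3 replicate 2, the first and last also without MUTEPPP#3 replicate 3, and the last without MUTE replicate 1). Depth limits little here, as 1 count is at most 0.00915 CPM. With 3 libraries per group, changes near 1.5-fold were mostly missed in simulated data. Only 200 genes were changed there, so this is not the sensitivity of MUTEPPP#3 against MUTE, where 5577 genes were called. The median absolute log2 fold change of those calls was 0.624.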

Other observations

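The genes in the first 2 paragraphs were chosen after their values were seen, apart from those that the rule for named genes holds, and no explanation is tested in this part.

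After *COPT2* (-6.02) and *FRO4* (-5.67) were seen among the largest falls in MUTEPPP#3, 7 further genes with roles in metal supply or superoxide removal were picked by their values. No list of copper genes was tested and other such genes were not looked up, so these values speak for single genes only. Against MUTE, the metal transporter genes *ZIP2* (-1.66, adjusted p = 4.75e-04) and *YSL2* (-1.62, adjusted p = 0.00201) and the copper chaperone gene *CCH* (-0.83, adjusted p = 0.00858) fell, and *FSD1*, the iron superoxide dismutase, went from 609 ± 22.4 to 282 ± 58.8 CPM (-1.11, SE 0.189, adjusted p = 0.00303). *CSD2*, the plastid copper/zinc superoxide dismutase, rose from 111 ± 17.3 to 452 ± 11.7 CPM (2.03, SE 0.191, adjusted p = 3.72e-04), its chaperone *CCS* by 1.27 (adjusted p = 3.72e-04) and the cytosolic *CSD1* by 1.14 (adjusted p = 0.00240). Against MUTEv5#2 and MUTEv5#5, *CSD2* was higher by 1.98 and 1.48, *CCS* by 1.32 and 0.96, and *FSD1* was at -1.16 and -1.20, while *CCH* against MUTEv5#2 did not pass (adjusted p = 0.0605). None of these 9 genes was called in a MUTEv5 line against MUTE. *COPT2* against MUTE was called under every alternative run; the 7 genes other than *COPT2* and *FRO4* were not run under the alternatives.

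Single loci set a line apart. AT3G01345 was at 186 ± 17.3 CPM in MUTEv5#2 and at 0.553 ± 0.458 in MUTE, 1.12 ± 0.674 in MUTEv5#5 and 1.80 ± 0.963 in MUTEPPP#3, and the noncoding AT2G06002 was at 7.89 ± 1.60 CPM in MUTEv5#2 against 0.487 ± 0.185 in MUTE and 0.628 ± 0.229 in MUTEv5#5. Of 1375 tested genes that are not annotated as protein coding, 46 were called in MUTEv5#2, 16 in MUTEv5#5 and 177 in MUTEPPP#3 against MUTE. Of 21261 protein-coding genes, 1094, 219 and 5400 were called. Between the MUTEv5 lines 8 of the 1375 and 7 of the 21261 were called.

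Members of lists that were not called also moved in MUTEPPP#3 against MUTE. Of 5 salicylic acid defence genes, *ICS1*, an enzyme of salicylic acid synthesis (-0.86, adjusted p = 0.00291), *EDS1* (-0.60, adjusted p = 0.00602) and the factor *WRKY70* (-1.77, adjusted p = 0.00588) fell, with a list adjusted p = 0.072. That list was called lower with fry (adjusted p = 0.0064), library totals as the only scaling (0.029), the clock index as a covariate (0.044) and without MUTE replicate 1 (0.024). Of 11 cold and abscisic acid genes, *RD29A* (3.58), *COR15A* (4.09) and *KIN2* (1.60) rose and *RD29B* (-2.33) fell, with a list adjusted p = 0.26 (0.026 without MUTEPPP#3 replicate 3). *RAB18*, a dehydrin gene of the same list, fell in MUTEv5#2 (-1.95) and MUTEv5#5 (-1.78).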
